A study of Mus musculus with 12 samples.

How the data were processed

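Mouse RNA was analysed in 12 libraries, 4 each of total lysate RNA (Input), of RNA precipitated with a control immunoglobulin (IgG IP) and of RNA precipitated with an antibody to CPEB4 (CPEB4 IP). Per the labels, all came from 3T3-L1 cells, a mouse preadipocyte line, brought to day 8 of adipogenic differentiation and then given free fatty acids for 24 h at 500 µM in total (300 µM palmitic, 100 µM oleic and 100 µM linoleic acid). Differentiation used 0.5 mM IBMX, 1 µM dexamethasone, 10 µg/mL insulin and 2 µM rosiglitazone until day 2 and insulin alone afterwards, per the labels. Of the groups, Input alone went through poly(A) selection, and libraries were amplified with 12 or 18 PCR cycles, per the labels, which do not say which library had which number. Groups and replicate numbers were taken from the sample titles, which also carry library numbers from 726 to 731 for replicates 1 and 2 and from 393 to 398 for replicates 3 and 4. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

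The authors deposited one table with a raw read count per library for 20586 transcript 3′ UTRs in mm10 coordinates, with Ensembl transcript identifiers and gene symbols. Per the submitters' processing notes, Bowtie 1.2.3, Bowtie2 2.2.2, featureCounts and DESeq2 1.22.1 were used on mm10. The order of the steps, the annotation release and whether counting used the strand are not stated, so overlapping genes and genes on opposite strands are given as uncertain where named. The deposited table also holds log2 normalised counts, which equal log2 of the count times one factor per library plus 1, and the group means of these log2 values. It further holds the authors' own DESeq2 log2 fold changes with their standard errors, p-values and adjusted p-values for CPEB4 IP against Input, for IgG IP against Input and for the interaction of both. The Wald statistics and the call of each feature (1, 0 or -1) are scores that the authors deposited. The authors' interaction calls followed the unadjusted p for all but 1 feature, which was tested on the table. Values below were computed from the deposited counts unless the authors' deposited table is named.

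Totals ranged from 88013 counts (IgG IP replicate 2) to 1578084 counts (Input replicate 4). A floor of 3 counts in one library corresponded to between 1.95 and 23.7 CPM (counts per 1e6, scaled by TMM). Intervals and floors cover counting error only, since reads from PCR without molecular identifiers are not independent molecules. The chi-square per degree of freedom between replicates of one group was lowest within replicates 1 and 2 and within replicates 3 and 4. It was 1.63 and 1.64 in IgG IP, 4.57 and 3.09 in CPEB4 IP and 10.9 and 25.9 in Input within these pairs, and 13.9 to 16.3, 20.1 to 33.8 and 32.6 to 40.7 across them. The precipitates may thus be 2 experiments with technical pairs, so n = 4 counts libraries and may overstate the number of independent samples. Of the features, 697 had no gene symbol (193 of those tested), and they held between 0.507% and 2.23% of the counts of a library. They were tested and counted but not named. Of the tested features, 1106 overlapped another feature. All columns of per-library values were mapped to samples.

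Counts were tested in R 4.3.3 with edgeR 4.0.16. Features were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 8680. Libraries were scaled by TMM, and all 12 were fitted in one quasi-likelihood model with a coefficient per group. Each of the 3 comparisons was tested with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the 8680 features, at an adjusted p of 0.05, and every adjusted p of a single gene comes from this test unless another is named. The standard error of a log2 fold change was taken as its size divided by the square root of F. Fold changes were computed with a prior count of 0.125. Where a group held 1 to 3 counts of a gene over its 4 libraries, the ratio of counts per scaled library size is given with its exact 95% interval, and where it held none, a lower bound against a floor of 3 counts over the group. A gene with several features was represented by the feature with the highest total count.

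Gene lists, 19 in number, were fixed before the data were examined, and 15 had at least 5 tested members. They covered CPEB family and poly(A) tail factors, immediate-early and AU-rich element genes, the unfolded protein response, signalling by TGF-beta, Wnt and insulin, adipogenic transcription factors, lipid metabolism, adipokines, chemokines and cytokines, extracellular matrix, cell cycle genes regulated by cytoplasmic polyadenylation in oocytes, histones, ribosomal proteins, nuclear-encoded and mitochondrially encoded respiratory chain genes, and markers of fibroblasts, brown adipocytes, macrophages, endothelium, and muscle or neurons. Lists were tested with camera (limma 3.58.1, voom weights, preset inter-gene correlation of 0.01), adjusted over the 15 lists, and again with an estimated correlation. Named genes were chosen by a rule fixed before the data were examined. For each comparison, these were the CPEB genes, the 10 largest changes each way among genes past the threshold with a mean log2 CPM of at least the median and the same sign in all 4 replicates, and up to 4 members per list with the smallest adjusted p past the threshold. Genes with only clone or accession names were passed over among the largest changes, 1 in each direction of each comparison. Other genes named, among them Lars2, Igfbp4, Sdhd, Klf6, Fabp4, Lpl, Scd1 and single members of lists, were chosen after their values were seen.

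Same-numbered libraries of different groups were checked for pairing after the group means were removed. The 12 correlations of same-numbered libraries across features lay between 0.120 and 0.467 (median 0.257), and those of different numbers within one range of library numbers between 0.124 and 0.412 (median 0.216). Across the ranges they lay between -0.440 and -0.0879. All same-number correlations were above 0.1, and a fit with the replicate number as a block is given where it changes a call. Named genes not past the threshold without the block were not checked for calls gained with it, except Cpeb2, Cpeb3 and Cpeb4. The pairing comes from the replicate numbers in the titles.

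The fits were tested on simulated counts for the 8680 features, with 50 genes changed at each of 4 folds. For CPEB4 IP against IgG IP, 6% of genes changed 2-fold, 24% of those changed 4-fold, 78% of those changed 8-fold and 92% of those changed 16-fold were recovered, with 2 false calls among 102. For CPEB4 IP against Input the shares were 4%, 38%, 70% and 88%, with 8 false calls among 108, and for IgG IP against Input 4%, 38%, 70% and 78%, with 7 false calls among 102. Of 15 unchanged lists, 0, 0 and 1 were called in the 3 comparisons, and the moved list was called in each. Genes were drawn independently in the simulation, so these counts do not test camera where list members are correlated. In the data the estimated correlation of ribosomal protein genes was 0.408 in CPEB4 IP against IgG IP and 0.718 in CPEB4 IP against Input.

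Alternatives fixed before the data were examined were DESeq2 size factors and library totals as scaling, no filter or a mean count of at least 50, DESeq2 1.42.0 (Wald test), voom with quality weights, a test against a log2 change of 1 (glmTreat), a replicate block, the range of library numbers as a term, only the groups compared, each replicate and each library left out, an estimated correlation and fry. Alternatives chosen after the data were seen were each range of replicates alone, both shallow IgG IP libraries left out, Lars2 left out, thinning of all libraries to 88013 counts, the range term and DESeq2 size factors for lists, and fits of the 8 IP libraries within ranges, with a block or with a replicate left out. Feature overlaps were found with GenomicRanges 1.54.1, and plots were drawn with Python 3.11.15 and matplotlib 3.10.9. A test of CPEB-binding motifs in the 3′ UTRs needs genome sequence and was not run. The authors' normalised values were not used for tests.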

Results

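RNA bound by CPEB4, a protein that binds 3′ UTRs and controls poly(A) tail length and translation, was compared with control precipitates and with total RNA in 3T3-L1 adipocytes exposed to free fatty acids. Per the labels, 3 groups of 4 libraries each were made: Input, IgG IP and CPEB4 IP. Reads were counted per 3′ UTR, and 8680 of 20586 features were tested. The Input libraries held 1418646, 1214274, 858028 and 1578084 counts in replicates 1 to 4. The IgG IP libraries held 116284, 88013, 369322 and 622976 counts, and the CPEB4 IP libraries held 1118341, 1132730, 1159188 and 1114911 counts. Between 8931 and 11404 features had a count in Input, between 8653 and 12677 in IgG IP and between 11746 and 16434 in CPEB4 IP. One feature, the 3′ UTR of Lars2 (mitochondrial leucyl-tRNA synthetase; mm10 chromosome 9, 123461679 to 123462664), held 46.3% ± 19.9 (SD, n = 4) of the counts in IgG IP, 13.3% ± 8.94 in CPEB4 IP and 10.5% ± 3.13 in Input. Its share in IgG IP was 28.6% and 29.7% in replicates 1 and 2 and 63.9% and 63.1% in replicates 3 and 4. In CPEB4 IP it was 7.26%, 4.60%, 17.7% and 23.7% in replicates 1 to 4. Whether these reads came from Lars2 RNA or from a repeat or an rRNA-like sequence was not tested.

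**Figure D1:**
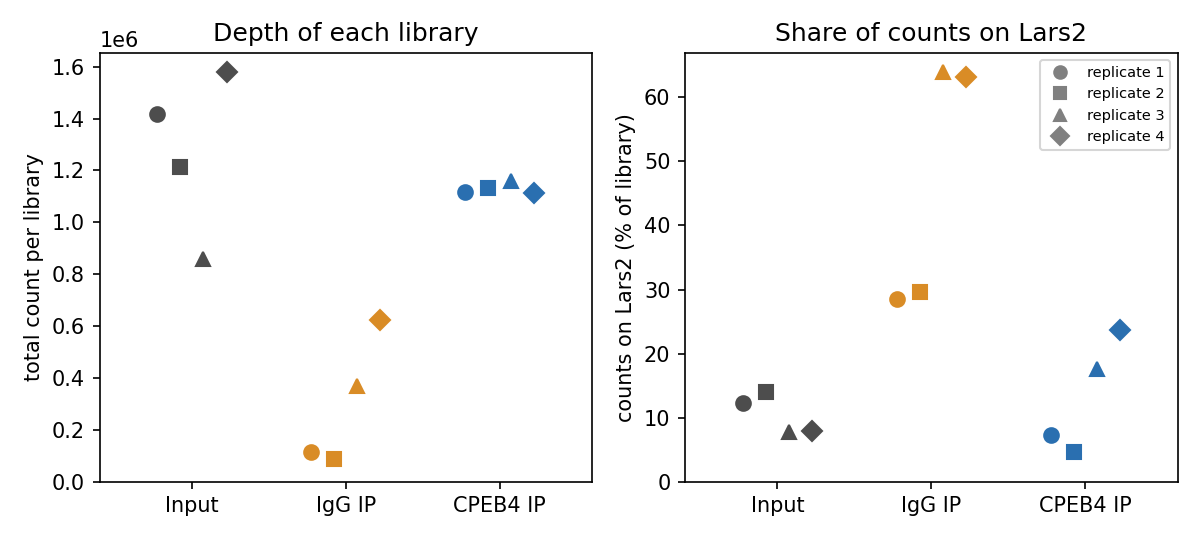
Total counts of each library and the share of counts on the Lars2 3′ UTR, by group and replicate. The IgG IP libraries hold the fewest counts (88013 to 622976) and the highest Lars2 shares (28.6% to 63.9%).

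The mRNA of Cpeb4 itself was more abundant in CPEB4 IP than in both controls in all 4 replicates. Its 3′ UTR (ENSMUST00000109412, mm10 chromosome 11, 31931533 to 31935634) stood at 1750 ± 222 CPM (SD, n = 4) in CPEB4 IP, 322 ± 66.6 CPM in IgG IP and 37.4 ± 31.2 CPM in Input. The log2 fold change was 2.44 (SE 0.50, adjusted p = 0.00867) over IgG IP and 5.55 (SE 0.57, adjusted p = 9.86e-07) over Input by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. IgG IP also held more Cpeb4 RNA than Input, by 3.11 (SE 0.52, adjusted p = 0.00019) on the log2 scale. Cpeb2 was higher in CPEB4 IP than in IgG IP by 2.40 (SE 0.61, adjusted p = 0.0277), on 1124 and 39 counts over 4 libraries. Cpeb3 had a log2 fold change of 2.02 (SE 0.68, adjusted p = 0.0919), which passed the threshold at 2.28 (adjusted p = 0.0387) with the replicate number as a block. Cpeb1, the family member best known from oocytes, had 32, 4 and 32 counts in Input, IgG IP and CPEB4 IP, with log2 fold changes of 0.31 (SE 1.216, adjusted p = 0.906) over IgG IP and 0.21 (SE 1.02, adjusted p = 0.874) over Input. The call of Cpeb4 over IgG IP was lost without replicate 1 (log2 fold change 2.21, adjusted p = 0.0580), replicate 2 (2.52, 0.0823) or replicate 4 (2.49, 0.0673).

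The comparison of CPEB4 IP with IgG IP asks which RNAs the CPEB4 antibody recovered beyond the background of precipitation. By camera at the preset correlation, 7 lists passed the threshold. Poly(A) tail factors, immediate-early genes, the unfolded protein response, signalling genes and adipogenic transcription factors were higher, and respiratory chain and ribosomal protein genes lower. With an estimated correlation 1 list passed, the poly(A) tail factors, and the respiratory chain, immediate-early and ribosomal protein lists had adjusted p = 0.105, 0.105 and 0.562. Among genes whose mean log2 CPM over all 12 libraries reached the median, the largest increases included G0s2, an inhibitor of adipose triglyceride lipase. It stood at 856 ± 280 CPM in CPEB4 IP and 39.98 ± 14.8 CPM in IgG IP (SD, n = 4; log2 fold change 4.39, SE 0.53, adjusted p = 0.000381; mm10 chromosome 1, 193272161 to 193272462). The matrix metalloproteinase Mmp11 was higher by 4.32 (SE 0.45, adjusted p = 0.000171; mm10 chromosome 10, 75923222 to 75923981). Nfkbia, the NF-kappaB inhibitor, was higher by 4.21 (SE 0.74, adjusted p = 0.00434), and the transcription factor Myc by 4.13 (SE 0.85, adjusted p = 0.00969). Rpn1, a subunit of the oligosaccharyltransferase, was higher by 3.96 (SE 0.61, adjusted p = 0.00198), and Cldnd1 by 3.85 (SE 0.45, adjusted p = 0.000327). Wbp5 and Tpra1 were higher by 4.17 and 3.97. The IgG IP side of some of these folds rested on few counts. IgG IP replicates 1 to 4 held 3, 1, 2 and 2 counts of Myc, 2, 0, 1 and 2 of Wbp5, and 3, 0, 1 and 2 of Tpra1. Ppib, the chaperone cyclophilin B, had 3 counts in IgG IP and 580 in CPEB4 IP, a ratio of 33.8 (95% counting interval 11.5 to 164), and overlaps Snx22 on the opposite strand. Hyal2, a hyaluronidase, had 2 and 185 counts, a ratio of 16.2 (95% counting interval 4.42 to 135). Of these genes, Ppib had a log2 fold change of -1.02 against Input (adjusted p = 0.056) and Hyal2 of -1.37 (adjusted p = 0.0393), whereas G0s2, Mmp11, Nfkbia, Myc, Wbp5 and Cldnd1 were also higher than Input.

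The list of CPEB family and poly(A) tail factors had the largest median change of the 15 lists. Of its 37 tested members, 14 were higher in CPEB4 IP than in IgG IP and 0 lower (18 higher adjusted over the list alone), with a median log2 fold change of 1.62 and a camera adjusted p of 1.29e-10 (adjusted p = 0.000889 with an estimated correlation). Tob1, which recruits the CCR4-NOT deadenylase, stood at 910 ± 211 CPM in CPEB4 IP and 75.9 ± 18.5 CPM in IgG IP (SD, n = 4; log2 fold change 3.58, SE 0.34, adjusted p = 0.000115; mm10 chromosome 11, 94214729 to 94215495). Its relatives Btg2 and Btg1 were higher by 3.26 (SE 0.51, adjusted p = 0.00198) and 1.76 (SE 0.29, adjusted p = 0.00285). Pabpc1, the cytoplasmic poly(A)-binding protein, was higher by 2.84 (SE 0.32, adjusted p = 0.000327). The deadenylase subunits Cnot7 and Cnot8, the poly(A)-binding protein inhibitor Paip2 and the poly(A) polymerase Papd5 were among the other members past the threshold. Of 29 immediate-early and AU-rich element genes, 5 were higher and 0 lower (5 adjusted over the list alone; median 1.30, camera adjusted p = 2.79e-05, adjusted p = 0.105 with an estimated correlation). They were Zfp36l1 (2.77, SE 0.35, adjusted p = 0.000466) and Zfp36 (2.94, SE 0.70, adjusted p = 0.0216), which bind AU-rich elements, the AP-1 subunit Jund (2.71, SE 0.47, adjusted p = 0.00399), the phosphatase Dusp1 (3.24, SE 0.80, adjusted p = 0.0251) and Klf6.

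Of 38 genes of the unfolded protein response, 8 were higher and 0 lower (10 adjusted over the list alone), with a median of 1.05, or 1.02 with the member without IgG counts at its bound (camera adjusted p = 0.00269, adjusted p = 0.266 with an estimated correlation). Among them were the stress transcription factor Atf4 (log2 fold change 2.64, SE 0.52, adjusted p = 0.00786), the oxidoreductase Ero1l (1.68, SE 0.35, adjusted p = 0.00966), the site-1 protease Mbtps1 (1.92, SE 0.44, adjusted p = 0.0181) and the chaperone Dnajb9 (1.32, SE 0.34, adjusted p = 0.028). For TGF-beta, Wnt and insulin signalling, 2 of 32 genes were higher and 0 lower (5 adjusted over the list alone; median 0.81, camera adjusted p = 0.00269, adjusted p = 0.266 with an estimated correlation). These were the Wnt co-receptor Lrp6 (1.91, SE 0.30, adjusted p = 0.00207) and the receptor Fzd7 (2.30, SE 0.58, adjusted p = 0.0268), whose feature overlaps another on the same strand. Of 26 adipogenic transcription factors, 5 were higher and 0 lower (5 higher and 1 lower adjusted over the list alone; median 0.71, camera adjusted p = 0.0478, adjusted p = 0.266 with an estimated correlation). They included Cebpb, an early driver of adipogenesis (2.51, SE 0.61, adjusted p = 0.0242), Stat5a (2.08, SE 0.48, adjusted p = 0.0181), which overlaps Stat3 on the opposite strand, Ebf1 (1.202, SE 0.31, adjusted p = 0.0311) and the glucocorticoid receptor Nr3c1 (1.06, SE 0.29, adjusted p = 0.0397). Klf2 had 1 count in IgG IP and 191 in CPEB4 IP, a ratio of 33.4 (95% counting interval 5.92 to 1326). The call of this list was lost without replicate 1, 2 or 3 (adjusted p = 0.0509, 0.0707 and 0.0868 by camera) and with DESeq2 size factors (adjusted p = 0.0668).

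Of 40 genes of adipocyte lipid metabolism, 3 were higher and 0 lower (8 higher and 2 lower adjusted over the list alone; median 0.36, camera adjusted p = 0.167, adjusted p = 0.5735 with an estimated correlation). They were G0s2, the fatty acid translocase Cd36 (1.91, SE 0.42, adjusted p = 0.0139) and hormone-sensitive lipase Lipe (1.61, SE 0.44, adjusted p = 0.038). By camera at the preset correlation the list had adjusted p = 0.0296 with the replicate number as a block, 0.0304 with library totals and 0.0402 with replicates 3 and 4 alone. The adipocyte genes Fabp4, Lpl and Scd1 had log2 fold changes of 1.2, 0.07 and -0.28 that did not pass the threshold (adjusted p = 0.128, 0.929 and 0.773). Of 18 adipokines, Vegfa (2.21, SE 0.34, adjusted p = 0.00188) and Nampt (1.60, SE 0.40, adjusted p = 0.0268) were higher and 0 lower (3 higher and 1 lower adjusted over the list alone). The list's median was -0.14 and its mean 0.09, with a camera adjusted p of 0.728 in the upward direction. Of 20 chemokines, cytokines and acute-phase factors, 1 was higher, Nfkbia, which restrains their transcription (median 0.77, camera adjusted p = 0.849), and the same held adjusted over the list alone. Of 45 extracellular matrix genes, 5 were higher and 1 lower (6 higher and 3 lower adjusted over the list alone). Besides Mmp11, the laminin chain Lamc1 (1.52, SE 0.30, adjusted p = 0.00786), the collagen Col6a1 (1.82, SE 0.36, adjusted p = 0.00786), Col4a1 and Lamb1 were higher. The list's median was -0.24, its mean 0.03 and its camera adjusted p 0.349 in the downward direction. The medians of the adipokine and matrix lists turned to 0.00311 and 0.00764 when libraries were scaled by totals alone.

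The proteoglycan Bgn, the matrix gene lower in CPEB4 IP, fell by 2.45 on the log2 scale (SE 0.36, adjusted p = 0.0015; mm10 chromosome X, 73494797 to 73495933), on 1611 counts in IgG IP and 1674 in CPEB4 IP. Of 79 nuclear-encoded respiratory chain genes, 16 were lower and 1, Sdhd, was higher (25 lower and 2 higher adjusted over the list alone; median -1.03, camera adjusted p = 1.29e-10, adjusted p = 0.105 with an estimated correlation and 0.0131 by fry). Examples were the ATP synthase subunits Atp5e (-1.93, SE 0.35, adjusted p = 0.00479) and Atp5d (-1.88, SE 0.39, adjusted p = 0.00974), the complex III subunit Uqcr10 (-2.01, SE 0.37, adjusted p = 0.00518) and the complex IV subunit Cox4i1 (-1.91, SE 0.38, adjusted p = 0.00785). The complex I subunits Ndufa5 (-2.52, SE 0.70, adjusted p = 0.0439) and Ndufv3 (-2.50, SE 0.62, adjusted p = 0.0246) fell further, but kept their calls under 19 of 37 and 23 of 38 alternatives, with Ndufv3 at -0.49 (adjusted p = 0.818) after thinning. Of 74 ribosomal protein genes, 6 were lower and 0 higher (8 lower adjusted over the list alone), with a median of -0.70, or -0.74 with 2 members at their bound (camera adjusted p = 1.89e-05, adjusted p = 0.562 with an estimated correlation and 0.405 by fry). Rpl28 (-2.96, SE 0.70, adjusted p = 0.0207), Rplp1 (-1.79, SE 0.40, adjusted p = 0.0149) and Rpl41 (-1.92, SE 0.44, adjusted p = 0.017) were among them, and Rpl35, which overlaps Wdr38 on the opposite strand, had -2.43. The ribosome biogenesis genes Bop1 and Rrp1 fell by 2.63 and 2.59, Tmem234 by 2.45, Fam160b2 by 2.91 and the autophagy adaptor Fyco1 by 2.49. Some of these decreases rested on few counts in both precipitates and arose from the scaling. Bop1 had 2, 1, 3 and 2 counts in IgG IP replicates 1 to 4 and 1, 2, 3 and 1 in CPEB4 IP. Rpl28 had 3, 3, 1 and 9 counts in IgG IP and 3, 5, 2 and 1 in CPEB4 IP. Ndufv3 had 2, 1, 5 and 11 counts in IgG IP and 1, 2, 8 and 6 in CPEB4 IP. The 113 lower genes held 13482 counts in IgG IP and 21253 in CPEB4 IP before scaling, and the Lars2 3′ UTR had a log2 fold change of -2.35 (SE 0.68, adjusted p = 0.0508).

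Of 8 tested fibroblast and preadipocyte markers, Vim was lower (-1.73, SE 0.40, adjusted p = 0.0193) and 0 higher (median -0.53, camera adjusted p = 0.293), and Des, the single tested muscle or neuron marker, was lower (-2.03, SE 0.51, adjusted p = 0.0265). The macrophage markers Lyz1, Csf1r and Mertk and the endothelial marker Flt1 had log2 fold changes of -0.97, 0.36, 0.27 and -1.47 (adjusted p = 0.68, 0.796, 0.851 and 0.581). Csf1r overlaps Hmgxb3 on the opposite strand. Of 6 brown adipocyte markers 0 passed (median 0.43, mean -0.30, camera adjusted p = 0.473 in the downward direction). Of 9 cell cycle genes known from oocytes, Myc was higher and 0 lower (median 0.82, camera adjusted p = 0.34). Of 11 histone genes, Hist1h1c, a linker histone, was higher (1.31, SE 0.32, adjusted p = 0.0253) and 0 lower (median -0.77, camera adjusted p = 0.293). Adjusted over the list alone, the numbers of these lists were the same. The deposited table listed 0 mitochondrially encoded genes.

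**Figure D2:**
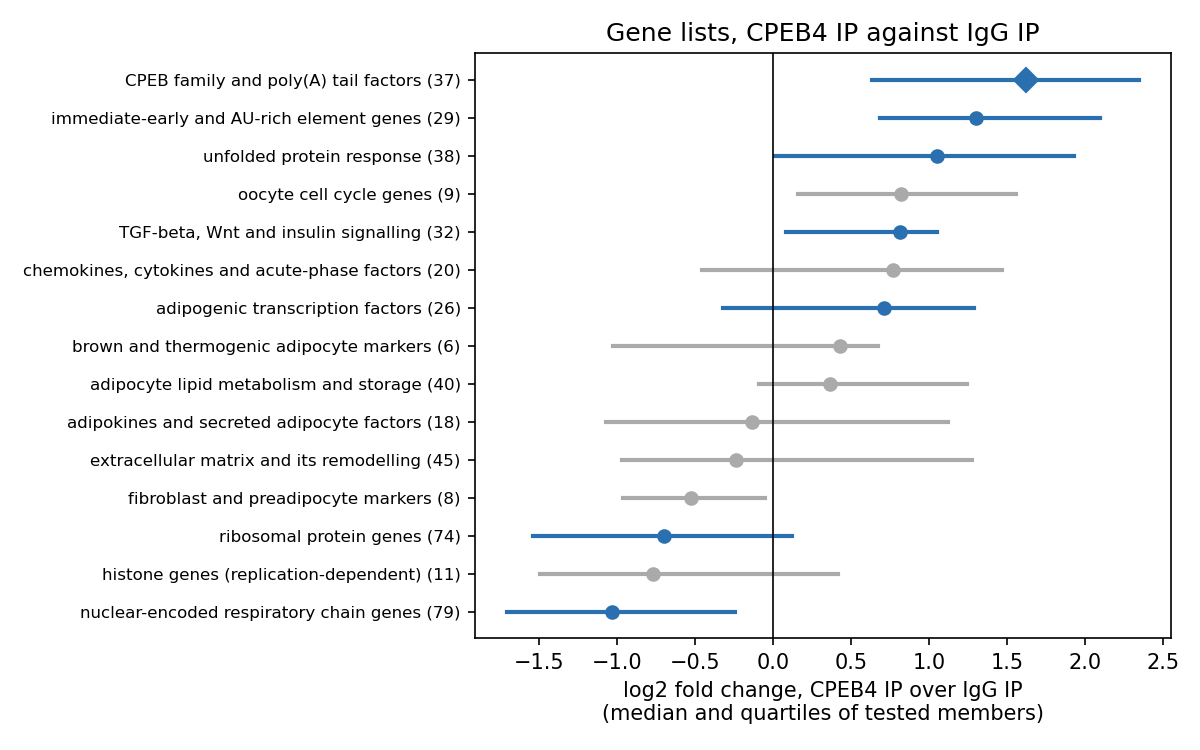
Median log2 fold change (point) with quartiles (line) of the tested members of each fixed gene list, CPEB4 IP over IgG IP, with the number of tested members. Blue lists passed camera at the preset correlation, and the diamond marks the list that also passed with an estimated correlation, the CPEB family and poly(A) tail factors (median 1.62).

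In all, 510 of 8680 features passed edgeR's quasi-likelihood test, 397 higher and 113 lower in CPEB4 IP than in IgG IP (1841 at an unadjusted p under 0.05). Of these, 508 had the same sign in all 4 replicates. The median of all features was 0.24 with TMM, -0.03 with DESeq2 size factors and 0.52 with library totals. The share of calls that were higher was 77.8%, 54.0% and 93.3%. It was 43.9% with a mean count of at least 50 (297 higher and 380 lower) and 49.8% with the DESeq2 Wald test (455 and 458), so the excess of higher calls depended on the processing. The count rested on the libraries used. It was 2, 37, 330 and 148 without replicates 1, 2, 3 and 4, and 966 without Input replicate 3. It was 323, 314, 236 and 251 without IgG IP replicates 1, 2, 3 and 4, and 135, 95 and 333 without CPEB4 IP replicates 1, 2 and 4. The 2 genes left without replicate 1 were Tob1 (log2 fold change 3.47, adjusted p = 0.0295) and Igfbp4, an insulin-like growth factor binding protein (2.90, adjusted p = 0.0322). The Input libraries set much of the spread: the biological coefficient of variation was 0.618 over all 12 libraries and 0.310 over the 8 IP libraries, which alone gave 2269 features, 1488 higher and 781 lower, with all 510 among them. All 510 had the same sign in replicates 1 and 2 as in replicates 3 and 4. The 510 were chosen on these same libraries, so the agreement of signs is in part set by that choice. Across all 8680 features the log2 fold changes of replicates 1 and 2 and of replicates 3 and 4 had a Pearson r of 0.457.

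**Figure D3:**
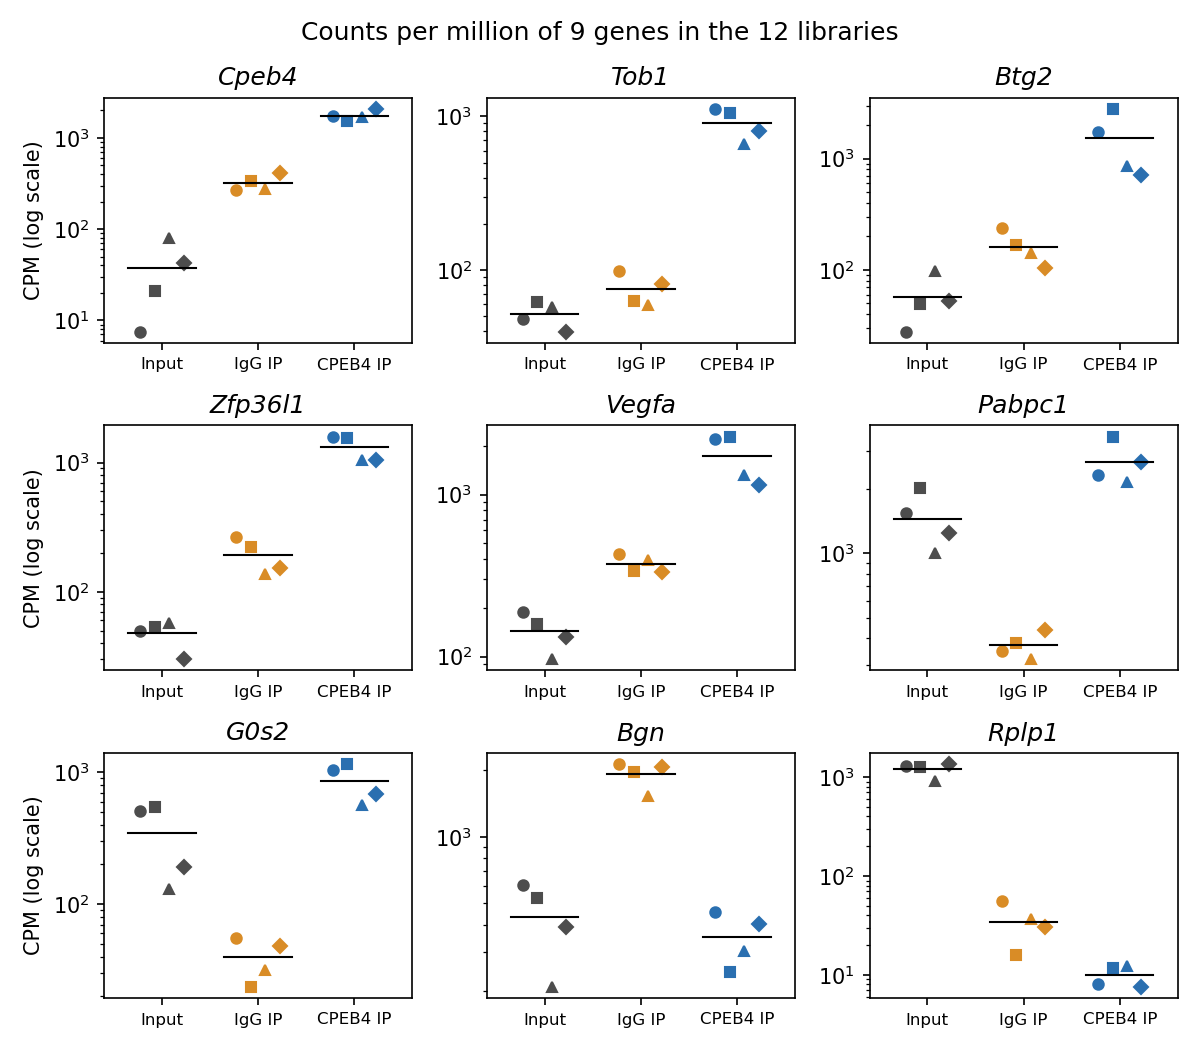
CPM per library (points, log axis) with group means for Cpeb4 and genes named in the text, in Input, IgG IP and CPEB4 IP. Cpeb4 lies between 1538 and 2062 CPM in the CPEB4 IP libraries, above the IgG IP libraries (267 to 409 CPM).

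In the authors' deposited table, the interaction of both precipitations was called higher for 433 features and lower for 624 by the unadjusted p, and 306 had an adjusted p past the threshold (130 higher, 176 lower). Of the 397 features higher here, 359 were called higher in the authors' deposited table, and of the 113 lower here, 112 were called lower there. By the adjusted p of the authors' deposited table, these numbers were 130 of the 397 and 104 of the 113. The log2 fold changes of CPEB4 IP over IgG IP and of the authors' deposited table had a Pearson r of 0.977 across the 8680 features, which are not independent replicates. Both come from the same libraries, and the interaction of both precipitations over Input also sets CPEB4 IP against IgG IP. The match was thus largely set in advance and is not independent evidence.

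Against Input, signalling genes, immediate-early genes and poly(A) tail factors were higher in CPEB4 IP, and respiratory chain and ribosomal protein genes lower, by camera at the preset correlation. With an estimated correlation 1 of these 5 lists passed, the poly(A) tail factors. Input was poly(A)-selected and the precipitates were not, per the labels, so the comparison also holds that difference in preparation. Of 32 TGF-beta, Wnt and insulin signalling genes, 25 were higher and 0 lower (25 adjusted over the list alone; median 2.43, camera adjusted p = 4.08e-06, adjusted p = 0.0582 with an estimated correlation). They included Lrp6 (4.84, SE 0.34, adjusted p = 2.32e-08), the insulin receptor Insr (4.22, SE 0.37, adjusted p = 2.14e-07), Bmpr1a (4.65, SE 0.46, adjusted p = 7.18e-07) and Tgfbr3 (3.71, SE 0.38, adjusted p = 9.75e-07). Of 29 immediate-early genes, 18 were higher and 1, Ier2, lower (the same numbers adjusted over the list alone; median 2.41, camera adjusted p = 0.000534, adjusted p = 0.106 with an estimated correlation). Among them were Dusp1 (6.53, SE 0.89, adjusted p = 1.68e-05) and Zfp36l2 (4.93, SE 0.59, adjusted p = 5e-06). Of the 37 poly(A) tail factors, 21 were higher and 2, Cnot1 and Cnot10, lower (22 and 2 adjusted over the list alone; median 1.71, camera adjusted p = 5.61e-05, adjusted p = 0.0262 with an estimated correlation). Of 79 respiratory chain genes, 72 were lower and 1, Atp5s, higher (73 and 2 adjusted over the list alone; median -4.72, camera adjusted p = 7.68e-25, adjusted p = 0.0582 with an estimated correlation). Of 74 ribosomal protein genes 71 were lower and 0 higher (71 adjusted over the list alone; median -4.49, camera adjusted p = 1.72e-20, adjusted p = 0.361 with an estimated correlation). The respiratory chain genes Ndufs6 and Ndufa4 fell by 7.91 and 5.94. The median 3′ UTR length was 90 bases for the ribosomal protein list, 175 for the respiratory chain list and 3012 for the signalling list. Among all tested features, those of 4 to 272 bases had a median log2 fold change of -3.996. Those of 2811 to 3795 bases had one of 1.41. Against Input the lists were not compared with random lists matched on length, so how far length accounts for their shifts was not tested.

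Adipocyte genes moved both ways against Input, as did the 8680 tested features as a whole (2396 higher and 2280 lower). Of 40 lipid genes, 15 were higher and 11 lower in CPEB4 IP (the same numbers adjusted over the list alone; median 0.37, mean 0.15, camera adjusted p = 0.911 in the downward direction). The triglyceride synthesis enzyme Dgat1 (-6.75, SE 0.53, adjusted p = 7.55e-08), fatty acid synthase Fasn (-3.24, SE 0.30, adjusted p = 4.02e-07) and the lipid droplet protein Plin2 (-3.95, SE 0.38, adjusted p = 5.66e-07) were lower, and caveolin Cav1 was higher (4.06, SE 0.42, adjusted p = 1.19e-06). Of 18 adipokines, 6 were higher and 9 lower (median -1.198, camera adjusted p = 0.179), with Agt, Retn and Cfd at -4.72, -6.36 and -6.77 and Vegfa at 3.59. Of 26 adipogenic factors, 10 were higher and 4 lower (median 0.63, camera adjusted p = 0.429), with Nr3c1 at 3.26, and the liver X receptor Nr1h3 (-7.52), Klf9 and Ncor1 among the lower. Of 20 chemokines, cytokines and acute-phase factors, Nfkbia, Csf1, Cxcl12 and Nfkb1 (4.58) were higher and Rela (-3.80), Mif (-3.79), C3 (-6.84) and Saa3 lower (median 1.16, camera adjusted p = 0.911). For the matrix list 14 were higher and 11 lower (median -0.30, mean 0.10, camera adjusted p = 0.911 in the downward direction), with Lama4 at -6.85 and Plod1 at -3.58. For the unfolded protein response 12 were higher and 5 lower (median 0.82, camera adjusted p = 0.465), with Ppp1r15b at 3.41 and Ddit3, which overlaps Mars on the opposite strand, at -5.87 (the other lower members were Edem2, Derl2, Calr and Trib3). Fibroblast markers had 1 higher (Pdgfrb, 3.13) and 1 lower (Vim, -5.39; median -0.81, camera adjusted p = 0.911). Oocyte cell cycle genes had 1 higher (Myc) and 0 lower (median 0.13, or -0.13 with DESeq2 size factors, camera adjusted p = 0.663). Brown adipocyte markers had 0 higher and 3 lower (median -1.51, camera adjusted p = 0.603): Cox8b (-4.62), Elovl3 (-2.22, overlapping Pitx3 on the opposite strand) and Cox7a1, with 3 counts in CPEB4 IP and a ratio of 81.4 (95% counting interval 27.6 to 398) in favour of Input. Among histones, H1f0 (2.34) and Hist1h1c (2.90) were higher and the near-identical Hist2h2aa1 and Hist2h2aa2, whose reads cannot be told apart with certainty, were lower (median -1.49, camera adjusted p = 0.663). Adjusted over the list alone, these numbers changed for chemokines (4 higher and 3 lower), the unfolded protein response (11 and 5) and brown adipocyte markers (1 and 3), and for no other list in this paragraph.

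The largest increases over Input were on genes near absent from Input, such as the splicing factor Cdc40 (log2 fold change 8.03, SE 0.80, adjusted p = 7.92e-07; 7 counts in Input and 1911 in CPEB4 IP), the kinase Stk4 (7.07, SE 0.77, adjusted p = 1.87e-06) and Fam107b (6.54, SE 0.75, adjusted p = 2.99e-06). Mpp5, Sipa1l2, Manea and Rap2c had log2 fold changes from 6.34 to 6.45. Smarcad1 had 2 counts in Input and 314 in CPEB4 IP, a ratio of 163 (95% counting interval 44.6 to 1348), and Adamts12, with 0 counts in Input, was at least 38.0-fold higher against a floor of 3 counts over the group. The largest decreases were Grhpr (-9.54, SE 0.67, adjusted p = 2.84e-08), Lrrc17 (-9.14, SE 0.61, adjusted p = 1.8e-08), Akap5 (-8.64, SE 0.65, adjusted p = 5.82e-08), Mvb12a, Mrpl54, Uqcrc1 and Blvrb. Ndufs8 and Eif3g had 3 counts and 1 count in CPEB4 IP against 1847 and 693 in Input, ratios of 595 (203 to 2886) and 669 (120 to 26470). Past the threshold were 4676 features, 2396 higher and 2280 lower (51.2% higher, 46.1% with DESeq2 size factors), with a median of all features of 0.29, and 4496 had the same sign in all 4 replicates. The higher features had a median 3′ UTR length of 2061.5 bases and the lower ones of 494, against 1344 for all tested.

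IgG IP against Input gives the background of the precipitation and its preparation, and it moved many of the same lists. Respiratory chain genes were lower in 69 cases and higher in 1 (Atp5s) of 79 (70 and 1 adjusted over the list alone; median -3.87, camera adjusted p = 2.75e-24, adjusted p = 0.0795 with an estimated correlation). Ribosomal protein genes were lower in 67 and higher in 0 of 74 (68 adjusted over the list alone; median -4.39, or -4.32 with 2 members at their bound, camera adjusted p = 3.55e-19, adjusted p = 0.398 with an estimated correlation). Signalling genes were higher in 17 and lower in 0 of 32 (19 adjusted over the list alone; median 1.82, camera adjusted p = 6.05e-06, adjusted p = 0.0795 with an estimated correlation). Pik3r1, a regulatory subunit of PI3-kinase, was higher by 3.71 (SE 0.43, adjusted p = 7.72e-06). Among all tested features, those with 3′ UTRs of 4 to 272 bases had a median of -3.73 in this comparison. Those of 2811 to 3795 bases had one of 1.14, and these lists were not matched on length here. Immediate-early genes were higher in 7 and lower in 1 (Ier2) of 29 (7 and 0 adjusted over the list alone; median 1.16, camera adjusted p = 0.0261, adjusted p = 0.355 with an estimated correlation), with Fosl2 at 2.86 (SE 0.50, adjusted p = 0.000309). Poly(A) tail factors were higher in 13 and lower in 5 of 37 (the same numbers adjusted over the list alone; median 0.65, camera adjusted p = 0.107, or 0.0496 without replicate 3, and adjusted p = 0.285 with an estimated correlation), with Msi2 at 1.91, and with Pabpc1 (-1.96), Cpsf1, Cpsf4, Cnot1 and Cnot10 lower. Matrix genes were higher in 9 and lower in 9 of 45 (median 0.29, camera adjusted p = 0.94), with the basement membrane protein Nid1 at 4.36 (SE 0.44, adjusted p = 2.09e-06) and Bgn at 2.15. Adipokines were higher in 3 (Vegfa and Apln among them) and lower in 9 of 18 (median -1.63, camera adjusted p = 0.1249), with Pltp, which overlaps Ctsa on the opposite strand, at -3.97.

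In the same comparison lipid genes were higher in 10 and lower in 14 of 40 (median -0.30, camera adjusted p = 0.621). Adipogenic factors were higher in 4 and lower in 2 of 26 (median -0.00334, or 0.0271 with DESeq2 size factors, mean 0.02, camera adjusted p = 0.832), with Ppargc1a at 2.06, Nr3c1, Ebf1 and Klf15 higher, and with Klf9 at -2.13 and Nr1h3 lower. Chemokines were higher in 2 (Cxcl12 at 3.13 and Nfkb1) and lower in 4 (Mif, Rela, C3 and Saa3) of 20 (median -0.28, camera adjusted p = 0.94). Unfolded protein response genes were higher in 7 and lower in 10 of 38 (median -0.31, camera adjusted p = 0.94), with Derl2 at -2.81. Fibroblast markers had 1 higher (Pdgfrb) and 1 lower (Vim; median -0.29, camera adjusted p = 0.94 in the upward direction), and brown adipocyte markers 0 and 3 (median -2.14, camera adjusted p = 0.685). Oocyte cell cycle genes had 0 and 0 (median -0.68, camera adjusted p = 0.94 in the upward direction) and histones 1 and 2 (median -0.17, camera adjusted p = 0.94). Adjusted over the list alone, the numbers changed for adipokines (5 higher and 9 lower), chemokines (2 and 3) and unfolded protein response genes (7 and 11), and for no other list without a camera call in this comparison. Adamts12 had 0 counts in Input and 99 in IgG IP and was at least 195-fold higher. Stk4, Mpp5, Slc10a7, Cdc40, Syne3, Hmbox1, Manea and Eea1 had log2 fold changes from 5.27 to 6.20. Dysf, Atpif1 and Psmb2 had 0 counts in IgG IP and were at least 49.4-fold, 32.0-fold and 31.7-fold lower than in Input. Past the threshold were 3594 features, 1521 higher and 2073 lower (42.3% higher, 34.5% with library totals), and the median of all features was -0.07. The higher features had a median 3′ UTR length of 2483 bases and the lower ones of 425.

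**Figure D4:**
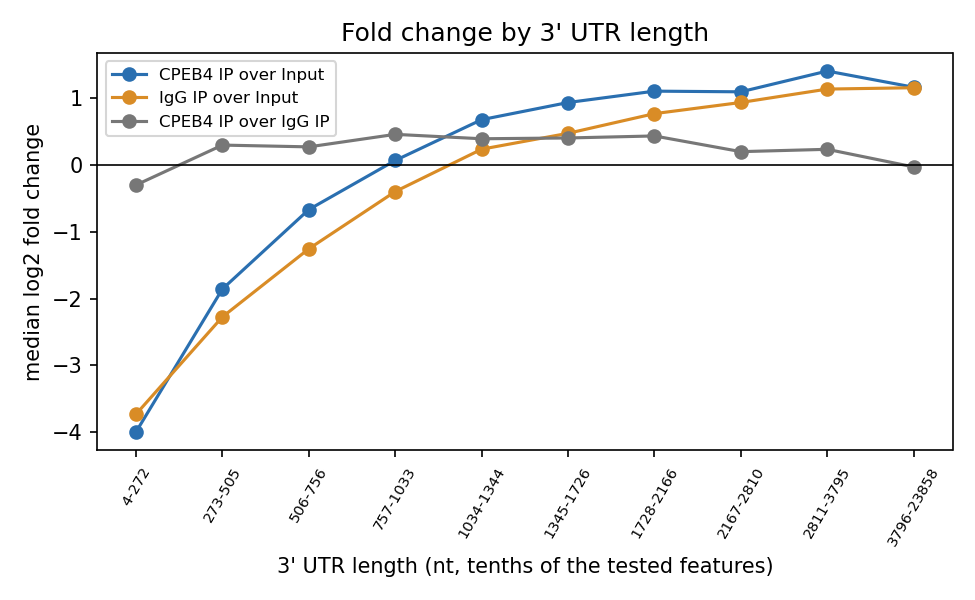
Median log2 fold change of the tested features in 10 bins of 3′ UTR length, for the 3 comparisons. From the shortest bin (4 to 272 bases) to the longest (3796 to 23858 bases) the median rises from -3.996 to 1.16 for CPEB4 IP over Input and from -3.73 to 1.16 for IgG IP over Input, and goes from -0.30 to -0.03 for CPEB4 IP over IgG IP.

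Of the 397 features higher in CPEB4 IP than in IgG IP, 265 were also higher than Input, 24 lower and 108 not past the threshold. The genes higher than both controls included Cpeb4, Tob1, Btg2, Btg1, Zfp36l1, Jund, Myc, Cebpb, Vegfa, Atf4, Lrp6, G0s2 and Cd36. In 162 of the 265 IgG IP did not differ from Input past the threshold, in 88 it was higher and in 15 lower. Of the 113 features lower than IgG IP, 101 were lower and 4 (Fyco1, Adamts12, Arf3 and Rgp1) higher than Input. Both comparisons share the CPEB4 IP libraries. Simulated groups without effect gave 0 shared calls, and independent lists of these sizes would share 110 higher and 29.7 lower. Groups without effect leave few calls to share, so that 0 does not measure how far shared libraries raise the overlap. With the CPEB4 IP libraries split between the comparisons the shared higher calls numbered 52 and 90 and the shared lower calls 3 and 20. The split also leaves fewer libraries per comparison, so its lower numbers mix that loss with the removed sharing. The count of 265 was 2, 21, 144 and 96 without replicates 1, 2, 3 and 4, and 408 without Input replicate 3. It was 163, 151, 118 and 135 without IgG IP replicates 1 to 4, 67 and 47 without CPEB4 IP replicates 1 and 2, and 167 with DESeq2 size factors. CPEB4 IP and IgG IP were higher than Input together for 1380 features and lower together for 1783, and 16 went opposite ways. With shared Input libraries, simulated groups without effect gave 0 for each, independent lists 420 and 545, and split Input libraries 1052 and 892 higher and 1578 and 1514 lower, with the same limits. The log2 fold changes of these comparisons had a covariance of 5.82, against 0.282 in the simulation (Pearson r 0.884 and 0.427 across features, and 0.718 and 0.716 with split Input libraries).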

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

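The tests of antibody binding, poly(A) selection, thinning, dilution, library depth and culture differences were chosen only after the result was seen, as was the comparison of standard errors before and after thinning, and the limits for thinning and dilution were set with their values known. Outlying samples were sought with Dixon's test in 390 groups of 4 values (127 named genes and 3 library measures). About 1 in 20, or 19.5, would be found by chance if the values were continuous and normal, and 28 groups held a sample far from the others. A group with counts in 1 library and 0 elsewhere is flagged whatever that count is. The 28 therefore cannot be read as an excess over 19.5. No library total, number of features with a count or Lars2 share stood out within its group.

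In Input replicate 1, Cdc40 (5.24 CPM), Stk4 (5.24), Smarcad1 (1.498), Mpp5 (3.00), Sipa1l2 (3.75), Manea (4.49), Nfkb1 (7.49), Slc10a7 (4.49), Syne3 (3.75) and Hmbox1 (7.49) had counts while the other Input libraries had 0, so their Input level rested on that library. Wbp5 was high in Input replicate 1 (43.4 CPM, others 12.1 to 17.3) and Cox4i1 low (1675 CPM, others 2428 to 2581). Bop1 was high in Input replicate 2 (333 CPM) and Tbrg1 low in Input replicate 3 (91.1 CPM). Rap2c (11.7 CPM) and Plin2 (1037 CPM) were high in Input replicate 4. In IgG IP, Rrp1 (86.8 CPM), Dnajb9 (126 CPM) and Sra1 (7.89 CPM) were high in replicate 2, Hyal2 (9.12 CPM), Rpl6 (9.12 CPM) and Tbrg1 (4.56 CPM) in replicate 3, and Klf2 (3.03 CPM) and Eif3g (3.03 CPM) in replicate 4. Of these, Sra1, Hyal2, Rpl6, Tbrg1, Klf2 and Eif3g had 0 counts in the other IgG IP libraries. In CPEB4 IP, Eif3g was high in replicate 1 (0.803 CPM, others 0), Plin2 high in replicate 3 (64.3 CPM), Cox7a1 low in replicate 1 (0 CPM, others 0.787 to 0.946) and Pltp low in replicate 2 (2.36 CPM). Eif3g in both precipitates, and Klf2, Sra1 and Tbrg1 in IgG IP, had 1 count in the library named. Cox7a1 had 0, 1, 1 and 1 counts in CPEB4 IP replicates 1 to 4.

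Features with longer 3′ UTRs were higher in both precipitates than in Input. Binding by the CPEB4 antibody alone was excluded as the cause, since IgG IP over Input rose with length as well. Spearman rho across features was 0.591 (0.342 to 0.643 by replicate number). Among features with a mean count of at least 50 over all 12 libraries rho was 0.703 (0.559 to 0.739). Input counts alone can carry a feature past this filter, so low counts on short 3′ UTRs in the precipitates were not excluded. Between the precipitates, which share a preparation, rho was -0.0146 over all features. It was 0.173 with a mean count of at least 50 (0.0854 to 0.133 by replicate number), so a weaker trend was present among features past that filter. Poly(A) selection of Input and recovery by the precipitation cannot be told apart, because no precipitate was poly(A)-selected and no Input was made without selection. No biological explanation was tested.

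The 113 features lower in CPEB4 IP than in IgG IP included 16 respiratory chain and 6 ribosomal protein genes, whose lists were lower by camera at the preset correlation and not with an estimated one (adjusted p = 0.105 and 0.562; by fry 0.0131 and 0.405). For the respiratory chain list the median of -1.03 lay at percentile 0.03 of 10000 random lists matched on length and expression (middle range -0.74 to 0.12). It was thus lower than in nearly all matched lists, which makes short 3′ UTRs less likely as its whole cause. They are not excluded, since random lists do not carry the correlation between members of this list (estimated at 0.121). The ribosomal protein list lay at percentile 3.52 (-0.72 to 0.22), so short 3′ UTRs could account for its shift. With all libraries thinned to one total, 57 of the 113 stayed lower and past the threshold (50.4%, exact 95% interval 40.9% to 59.98%), all 113 stayed below 0, and their median went from -1.87 (SD across genes 0.41) to -2.07 (SD 0.75). In the 56 that lost the call the standard error rose in all (median 0.46 to 0.78) and the fold change moved nearer 0 in 38 (median -1.87 to -1.62), so the part played by shallow IgG IP libraries stays open. Background RNA diluted by enriched RNA in CPEB4 IP is a candidate explanation that the tables do not decide: the median raw count ratio of these genes was 0.831, 1.222, 2.09 and 1.204 times that of Lars2 in replicates 1 to 4, but genes chosen for a low scaled ratio lie near Lars2 in part by their selection, the origin of the Lars2 reads was not tested, and the amount of RNA recovered was not analysed here.

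The CPEB4 IP libraries of replicates 1 and 2 differed from those of replicates 3 and 4 at 2075 features by edgeR's quasi-likelihood test, against 359 in IgG IP and 0 in Input (1075 at an unadjusted p under 0.05). Depth was excluded, since the mean totals of both pairs had a ratio of 1.01 and 2258 features passed after thinning. Without Lars2 2114 features passed, so the calls did not rest on its own counts. Libraries were scaled by TMM, which limits the pull of 1 feature, so this test could hardly have come out otherwise. A difference of the cultures before precipitation may contribute but cannot be told apart from handling of the precipitates, with a Pearson r across features of 0.309 between this difference in CPEB4 IP and in Input, and of 0.333 with IgG IP. The difference of CPEB4 IP from IgG IP itself did not pass an interaction test with the range at any feature with all 12 libraries (0 by edgeR, 240 at an unadjusted p under 0.05) and passed at 4 with the 8 IP libraries (759 at an unadjusted p under 0.05).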

How the results depend on the processing

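Fits of replicates 1 and 2 alone or 3 and 4 alone, without IgG IP replicates 1 and 2, without Lars2, with thinned libraries, of lists with the range term or DESeq2 size factors and of the 8 IP libraries within ranges, with a block or with a replicate left out were chosen after the data were seen. No named gene and no list past the threshold changed direction under any alternative, but the balance of calls did, from 397 higher and 113 lower to 297 and 380 with a mean count of at least 50 and to 455 and 458 with the DESeq2 Wald test. Medians of 4 lists that did not pass changed sign with the scaling: adipokines (-0.14 to 0.00311) and matrix genes (-0.24 to 0.00764) against IgG IP with library totals, and with DESeq2 size factors oocyte cell cycle genes in CPEB4 IP (0.13 to -0.13) and adipogenic factors in IgG IP (-0.00334 to 0.0271) against Input. For CPEB4 IP against IgG IP, 510 features became 913 with the DESeq2 Wald test (500 of the 510 among them), 2418 with voom and quality weights, 881 with the range of library numbers as a term, 2269 with only the groups compared, 61 with a log2 change tested against 1, 109 without IgG IP replicates 1 and 2 and 0 with replicates 3 and 4 alone (edgeR, 1168 at an unadjusted p under 0.05), against 407 with replicates 1 and 2 alone (289 of the 510 among them). All 510 were among those of voom, of the range term and of the groups compared alone. With the 8 IP libraries the count was 1420 within replicates 1 and 2, 2645 within replicates 3 and 4 and 3145 with a replicate block. Leaving out 1 replicate or library gave 2 to 966 with all groups in the fit. With the 8 IP libraries alone it gave 1623, 1507, 1610 and 1275 without replicates 1 to 4 and kept 478 to 495 of the 510. The estimated spread was 0.618 with Input and 0.310 without it; the cause of the shifts was not tested. The features higher than both controls (265) became 167 with DESeq2 size factors, 1130 with voom, 473 with the range term, 32 with a log2 change tested against 1, 53 without IgG IP replicates 1 and 2 and 0 with replicates 3 and 4 alone (208 with replicates 1 and 2 alone), and 2 to 408 with 1 replicate or library left out; the cause was not tested. The DESeq2 Wald test gave 298. CPEB4 IP against Input (4676) fell to 2482 and IgG IP against Input (3594) to 2230 with a mean count of at least 50, where fewer genes were tested, and ranged from 3670 to 5265 and from 2697 to 4474 with 1 replicate or library left out. Lists past the threshold numbered 7, 5 and 4 in the 3 comparisons, 1, 1 and 0 with an estimated correlation, and 6, 10 and 7 with fry, which tests each list on its own. By fry the ribosomal protein list had an adjusted p of 0.405 and the respiratory chain list of 0.0131 in CPEB4 IP against IgG IP. The call of the adipogenic list was lost with DESeq2 size factors (adjusted p = 0.0668), without replicates 1, 2 or 3, without IgG IP replicates 1 and 2 (0.121), without Lars2 (0.0655), with replicates 1 and 2 alone (0.0787) and after thinning (0.174). The log2 fold change of Cpeb4 over IgG IP stayed at 2.44 but missed the threshold when tested against 1 (adjusted p = 0.0894), and was 2.45 with replicates 3 and 4 alone (0.137), 2.35 without IgG IP replicates 1 and 2 (0.109) and 2.17 to 2.59 with 1 replicate or library left out. With the replicate number as a block the counts were 672, 4862 and 3718 features and 375 higher than both controls. Among lists the block changed the call of the lipid list alone. No call of a named gene was lost with the block, and that of Cpeb3 was gained. Of named genes not past the threshold in the main fit, only Cpeb2, Cpeb3 and Cpeb4 were followed, so gains of others would not show. Of the named-gene results of CPEB4 IP against IgG IP, 379 of those with 1 replicate or library left out and 243 under other alternatives lost the threshold, 856 and 858 stayed on their side of it, and 5 and 10 gained it. All of these gains were of Cpeb3. Tob1 kept its call under 37 of 38 alternatives, G0s2, Mmp11, Pabpc1, Rpn1, Ppib, Cldnd1, Zfp36l1, Bgn and Tmem234 under 36, Cebpb under 23, Cpeb2 under 21, Lipe under 19, Bop1 under 16, Ebf1 and Hist1h1c under 15, Dnajb9 under 13 and Nr3c1 under 12. The alternatives for CPEB-binding motifs were not run. Depth limits the IgG IP side most, where 3 counts correspond to between 9.09 and 23.7 CPM per library.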

Other observations

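The gene families in this part were chosen only after the values were seen. Members named above by the fixed rule were left out of them unless stated, with the repeat that puts them back added last. Genes named after their values were seen, Lars2 among them, were not subject to this omission. The hypotheses on membrane proteins and on mitochondrial proteins were tested with these families, and the comparisons with other splits of the samples were planned.

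Aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, had a median log2 fold change of -0.58 in CPEB4 IP over IgG IP across 17 tested genes. No member passed the threshold alone, the camera adjusted p was 0.00468 over 10 added families and adjusted p = 0.313 with an estimated correlation, and the median lay at percentile 3.02 of random lists matched on 3′ UTR length and expression. Subunits of the translocon and oligosaccharyltransferase of the endoplasmic reticulum, related to Rpn1, had 4 of 34 members higher (Ssr2, Ostc, Tram1 and Sec61a1) and 0 lower, with a median of 0.50 and a camera adjusted p of 0.203. Of 38 proteasome subunits, Psmd7, Psmd11 and Psma1 were higher and 0 lower (median 0.53, camera adjusted p = 0.665). Of 46 translation initiation factors, 2 were higher and 2 lower (Eif1, Eif4h, Eif2ak3 and Eif3l; median -0.10, camera adjusted p = 0.203). Of 28 kinesins and dyneins, Dync1h1 was lower and 0 higher (median -0.32, camera adjusted p = 0.203), of 150 zinc finger genes Zfp280c was higher and 0 lower (median 0.18, camera adjusted p = 0.665), and of 16 V-type ATPase subunits 0 passed (median -0.06, camera adjusted p = 0.665).

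Several of the largest increases in CPEB4 IP were on membrane or secretory pathway genes, and a candidate explanation was that RNAs of membrane proteins as a class were recovered more. Of 152 solute carriers 6 were higher and 2 lower, and their median of 0.32 lay at percentile 76.4 of 10000 matched random lists (middle range 0.00242 to 0.46), with a camera adjusted p of 0.697. Of 118 Tmem genes 4 were higher and 1 lower (median 0.38, camera adjusted p = 0.697). The tests did not bear the hypothesis out for these families. A second hypothesis was that RNAs of mitochondrial proteins in general were recovered less. The 65 mitochondrial ribosomal proteins had a median of 0.07 at percentile 37.7 of matched random lists (-0.33 to 0.56), with 2 higher and 1 lower (Mrpl10, Mrpl2 and Mrpl12) and a camera adjusted p of 0.203 in the downward direction, but Mrpl54, which was lower (-3.46, adjusted p = 0.00743 by edgeR), had been left out. With it, 2 of 66 were higher and 2 lower, and the median of 0.07 lay at percentile 41.6 (camera adjusted p = 0.162, and 0.764 with an estimated correlation), so a shift of this family was not shown. With Tmem234 and Slc10a7 put back, 4 of 119 Tmem genes were higher and 2 lower (camera adjusted p = 0.818), and 6 of 153 solute carriers were higher and 2 lower (camera adjusted p = 0.811). With Zfp36l1, Zfp36 and Zfp36l2 put back, 3 of 153 zinc finger genes were higher and 0 lower (median 0.21, camera adjusted p = 0.818). With Psmb2 put back, the median of 39 proteasome subunits was 0.62 at percentile 97.8 of matched random lists (-0.61 to 0.59; 95.7 without it), with 3 higher and 0 lower and a camera adjusted p of 0.725. With Eif3g put back, 2 of 47 initiation factors were higher and 2 lower (median -0.10, camera adjusted p = 0.162). From the other families no member had been left out. The translocon and oligosaccharyltransferase family had 34 tested members in both versions, so Rpn1 was counted in neither.

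For each comparison the 8 libraries were split in all 35 ways into 4 and 4 and tested again with edgeR. In CPEB4 IP against IgG IP, 1 of the 35 splits, the real one, gave 510 features or more, and the highest other split gave 0 (555 at an unadjusted p under 0.05 against 1841 for the real split). In CPEB4 IP against Input, 1 split gave 4676 or more and the highest other gave 0 (945 at an unadjusted p under 0.05 against 5098). In IgG IP against Input, 1 split gave 3594 or more and the highest other gave 6. For the features higher than both controls, 1 split of the 8 IP libraries gave 265 or more and the highest other gave 0. With the 8 IP libraries fitted without Input, the real split gave 2269 and the highest other 34, for the split of replicates 1 and 2 from replicates 3 and 4. The 35 splits treat the libraries as exchangeable, although same-numbered libraries correlated at 0.120 to 0.467 across features and libraries of different ranges at -0.440 to -0.0879. Every other split also mixed libraries of both groups, so a real difference between the groups adds to the spread within them and lowers the calls. One such split of CPEB4 IP and IgG IP gave 15 features at an unadjusted p under 0.05 by edgeR. The low numbers of the other splits thus do not measure how many calls chance would give. Among the 8 splits that part all 4 same-numbered pairs the highest other gave 0 in each comparison, and 8 splits are too few for a share under 0.05.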
